A study of Mus musculus with 8 samples.

How the data were processed

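RNA from the duodenum of 8 female Mthfr heterozygous mice was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, whose features cover whole transcripts. Per the labels' protocols, mice of both strains were fed from weaning for 1 year on a control diet with 2 mg folate per kg or a low folate diet with 0.3 mg per kg. Both diets contained 1% of a sulfonamide that limits folate made by gut bacteria. All 8 samples are labelled as low folate. Per the same protocols, intestines were examined under a dissecting microscope for tumours, normal intestine was frozen, and 100 ng of total RNA was labelled per array. Samples were grouped by the strain in their labels, 4 BALB/c and 4 C57Bl/6, and the labels number the samples of each strain as biological replicates.

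The authors deposited 1 table of values with 35528 features and 8 columns. The deposited values were taken as log2 expression from their range and shape, since the log base, the background correction and the normalization were not given in the sources used here. Array minima lay between 0.127 and 0.442 and maxima between 13.2 and 13.5. The columns nearly shared their quantiles, with a mean absolute gap of 0.00899 to 0.0295 from the mean quantile, so no further normalization was applied. A method that forces columns onto shared quantiles hides a shift of most genes in one direction, so the counts of higher and lower genes are relative to the rest of the array. No detection calls were used here. Values near the lower quartile of an array (2.93 to 2.98) were treated as dim, and folds against them may be compressed. Probe sequences were not used here, so a lower signal from a strain variant under a probe was not separated from a lower transcript level.

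Features were named through the platform annotation, which listed 23387 of them. Of these, 21767 had 1 gene symbol and were used, and 1620 had several and were left unnamed. A further 12141 features were unnamed in that table. The Entrez identifiers of 21676 features were found in a mouse gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used only for names, chromosomes and the order of neighbouring genes. Each of 19918 genes was represented by 1 feature, the one with the highest mean over the 8 arrays in the 997 genes that had several. A gene was tested if at least 4 arrays exceeded their own 25th percentile, which kept 16767 genes and left out 3151.

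Differences, BALB/c minus C57Bl/6, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, strain as the only term, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Fold changes are ratios of group geometric means. The 39 gene lists, 1051 genes in all, came from textbook knowledge of the duodenum, folate, intestinal tumours, strain differences and other cell types, and 885 of their genes were tested. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The 38 lists with at least 5 genes tested were compared with all other genes by camera, with its preset correlation of 0.01 and with an estimated correlation. They were also tested by fry, which sets a list against no change and not against other genes. Chromosomes were compared with Fisher's exact test, and neighbouring calls with 10000 permutations of the calls over genes. The genes counted beside Mthfr were the 100 tested on either side.

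The genes named were Mthfr and the measured strain reference genes, then the 12 highest and 12 lowest log2 differences among called genes whose strains did not overlap, leaving out symbols of the form Gm plus digits, ending in Rik or starting with LOC, and then up to 4 members with the smallest p in each list described. Genes named outside this rule are said to have been chosen after their values were seen. The pancreatic score of an array was the mean log2 value of the 18 tested genes of the exocrine pancreas list, and arrays were called high above 7.5.

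The alternatives were quantile normalization and median centring of the columns, no filter and a stricter filter at the 50th percentile, other rules for genes with several features, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array, all features, a threshold of 0.01, an unadjusted p with a 1.5-fold change, and other set tests. After the data were examined, the pancreatic score was added as a covariate, and the arrays with high and with low scores were each analysed alone. The fit was tested on simulated data of 16767 genes with 200 changed, made with the means and spread of this comparison. It called 85% of the genes changed 1.5-fold and 94% of those changed 2-fold, all called ones with the right sign, and 7 unchanged genes. In the simulation 0 lists were called with no list shifted, and a list shifted by 0.3 was called. The simulated genes varied independently of one another. The simulation therefore does not show how often camera calls a list falsely when its genes vary together.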

Results

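Transcript abundance was measured in the duodenum of 8 female mice, 4 of the BALB/c strain and 4 of the C57Bl/6 strain, each on its own Affymetrix Mouse Gene 1.0 ST array. All animals carried 1 disrupted copy of Mthfr, the gene for the folate enzyme methylenetetrahydrofolate reductase. All had been fed a low folate diet with 0.3 mg folate per kg for 1 year. The labels describe the arrays of a strain as biological replicates, and the tissue frozen for study as normal intestine. Mthfr had no named feature in the probe annotation and was not analysed here, so the genotype in the labels was not checked against expression. The array medians lay between 4.45 and 4.51 on the log2 scale. Across genes, arrays of the same strain correlated at a Pearson's r of 0.978 to 0.993 and arrays of different strains at 0.964 to 0.984. Genes are not independent replicates, and no pair of arrays held identical values. The number of arrays, 4 per strain, limits the precision of every value below.

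The strains were compared to find transcripts that differ between the duodenum of BALB/c mice, a strain in which duodenal tumours had been seen, and that of C57Bl/6 mice. The secreted phospholipase gene Pla2g2a stood 49-fold higher in BALB/c, and the class II histocompatibility gene H2-Ea measured 8.82 there against 3.16 in C57Bl/6 (log2 means). St3gal4, which encodes a sialyltransferase, stood 41.2-fold higher in C57Bl/6. Of 46 fatty acid oxidation genes 27 were higher in BALB/c and 0 lower, and of 34 cell cycle genes 17 were lower and 0 higher. The corresponding lists passed with the preset correlation of limma camera but not with an estimated one (adjusted p = 0.215 and 0.26). Of 16767 genes tested with limma, 1747 (10.4%) passed an adjusted p of 0.05, of which 733 were higher and 1014 were lower in BALB/c. The excess of lower genes depended on the processing, with 811 higher and 793 lower after quantile normalization of the columns and 245 higher and 222 lower at an unadjusted limma p under 0.05 with a 1.5-fold change. Lower genes stayed more numerous without BALB/c replicate 2 (536 higher, 663 lower) and with the pancreatic score in the model (588 higher, 666 lower). Centring each array on its median widened the excess, with 612 higher and 1251 lower. Of the 1747 called genes, 434 changed at least 1.5-fold, 222 higher and 212 lower, and 138 at least 2-fold, 64 higher and 74 lower. In 3037 genes (18.1%) all 4 arrays of one strain lay above all 4 of the other, against 2.86% by chance, and 1647 of the called genes were among them. Transcripts of the exocrine pancreas were abundant in 5 of the 8 arrays, 3 from BALB/c and 2 from C57Bl/6. Within those 5 arrays 566 genes passed, and within the other 3 arrays, which hold a single BALB/c array assumed to vary like the C57Bl/6 arrays, 175 passed, 90 higher and 85 lower.

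Pla2g2a and H2-Ea belonged to a list of 12 genes known for differing between laboratory strains, of which 10 were tested. C57Bl/6 mice are known to carry a frameshift in Pla2g2a and a promoter deletion in H2-Ea. Pla2g2a (feature 10509584, chromosome 4) measured 10.20 ± 0.16 in BALB/c and 4.59 ± 0.22 in C57Bl/6 (log2, mean ± SD, n = 4 each), a log2 difference of 5.61 with a standard error (SE) of 0.11. H2-Ea (feature 10450161, chromosome 17) measured 8.82 ± 0.19 and 3.16 ± 0.16, a log2 difference of 5.65 (SE 0.11). The glyoxalase gene Glo1 was higher by 1.34 (SE 0.13), the guanylate-binding protein gene Gbp2b by 0.40 (SE 0.09) and Nnt, the mitochondrial transhydrogenase gene, by 0.30 (SE 0.07). The other 5, Prkdc (-0.11), Cdkn2a (0.01), Ahr (0.10), Mx1 (-0.12) and Mx2 (0.18), did not pass, and the count was also 5 higher and 0 lower when adjusted over the list alone. The list passed towards higher values in BALB/c (limma camera, adjusted p = 2.3e-05; adjusted p = 0.101 with an estimated correlation), with a mean of 1.34 and a median of 0.24, since H2-Ea and Pla2g2a lay far above the rest.

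**Figure D1:**
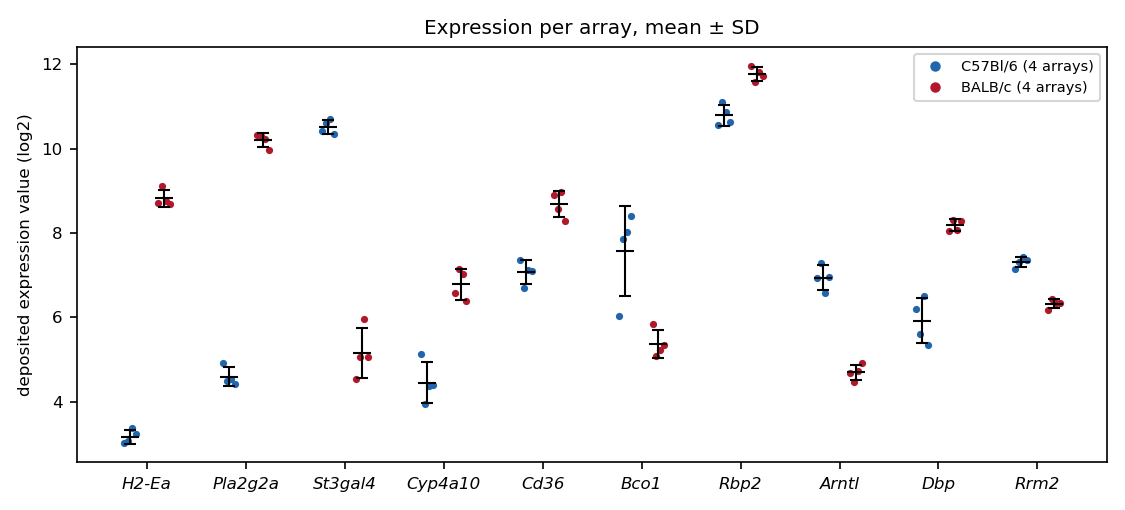
Deposited log2 expression values of 10 named genes in each array, with C57Bl/6 arrays in blue and BALB/c arrays in red, and bars for the mean and SD of 4 arrays. H2-Ea and Pla2g2a lie near 9 and 10 in BALB/c against 3.16 and 4.59 in C57Bl/6, and St3gal4 lies at 10.52 in C57Bl/6 against 5.15. The strains overlap in none of the 10 genes, which the naming rule favours, since it takes non-overlapping genes and those with the smallest p in a list.

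Among the other genes with the largest increases in BALB/c, Abhd1 (8.03-fold) and Paqr7, a membrane progestin receptor gene (7.24-fold; log2 difference 2.86, SE 0.09), were followed by the interferon-induced gene Ifi44l (2.55, SE 0.15). Mt2, a metallothionein gene that binds zinc and copper, was 5.65-fold higher (SE 0.41 on the log2 scale). Its log2 difference was 2.73 within the arrays rich in pancreatic transcripts and 2.13 with the pancreatic score in the model. Within the arrays low in these transcripts, which hold a single BALB/c array, it was 1.42. The remaining increases included Pck1 (2.25, SE 0.49), a gene of gluconeogenesis, Me1 (2.07, SE 0.15), which encodes malic enzyme, the pentraxin gene Mptx1 (2.12, SE 0.23) and Ugt2b38 (2.01, SE 0.29), a glucuronosyltransferase gene. St3gal4 (feature 10592084, chromosome 9) showed the lowest BALB/c value relative to C57Bl/6, at 5.15 ± 0.59 against 10.52 ± 0.17 (log2, mean ± SD, n = 4 each). AI506816 followed at -4.90 (SE 0.14), then the TRIM family genes Trim12a at -4.65 (SE 0.18) and Trim30d at -3.36 (SE 0.14), and the class I histocompatibility gene H2-Q2 at -3.61 (SE 0.12). The deiodinase gene Dio1 (-2.48, SE 0.11), the phosphate transporter gene Slc34a2 (-2.42, SE 0.33), the receptor gene Gpr151 (-2.57, SE 0.30) and the apolipoprotein L genes Apol7c (-2.27, SE 0.25) and Apol10a (-2.02, SE 0.25) were also lower in BALB/c. Trim12a, Trim30d, H2-Q2 and Ugt2b38 belong to families of closely related genes whose probes can bind transcripts of relatives, so their values are uncertain as to the member. The means of Ifi44l (2.80), H2-Ea (3.16) and Mptx1 (3.29) in C57Bl/6 and those of Trim12a (2.82) and Apol10a (2.96) in BALB/c lay near or below the lower quartile of an array, so these folds depend on values near the dim end of the scale. The adjusted p of Pck1 was 0.014 and rose to 0.086 with an intensity trend and a robust prior in the limma fit. Its log2 difference was 1.56 within the arrays rich in pancreatic transcripts (limma, adjusted p = 0.154) and 3.84 within the remaining arrays, which hold a single BALB/c array.

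Of 46 genes of PPARA signalling and fatty acid oxidation tested, 27 were higher in BALB/c, 0 were lower and 19 did not pass, and adjusted over the list alone 37 were higher and 1 was lower. The median log2 difference was 0.50 (limma camera, adjusted p = 4.89e-19; adjusted p = 0.215 with an estimated correlation). Cyp4a10, a fatty acid omega-hydroxylase gene, measured 6.78 ± 0.36 in BALB/c and 4.45 ± 0.49 in C57Bl/6, a 5.02-fold difference. Cd36, which encodes a fatty acid transporter, was higher by 1.62 (SE 0.16), the acyl-CoA thioesterase gene Acot1 by 1.40 (SE 0.15) and the peroxisomal thiolase gene Acaa1a by 0.84 (SE 0.08). Ppara itself, the nuclear receptor gene of the list, was higher by 1.16 (SE 0.16), and Cpt1a, which encodes the enzyme of mitochondrial fatty acid entry, by 0.70 (SE 0.08), both named after their values were seen. Cyp4a10 and Acot1 have close relatives on the array. With the pancreatic score of each array in the model 28 members were higher, and within the 5 arrays rich in pancreatic transcripts 18 were higher and 1 was lower.

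Of 43 retinoid metabolism and signalling genes tested, 12 were higher in BALB/c, 2 were lower and 29 did not pass, and adjusted over the list alone 13 were higher and 3 were lower. Adh4, an alcohol dehydrogenase gene, was higher by 1.39 (SE 0.14), Rbp2, the cellular retinol-binding protein gene of enterocytes, by 0.98 (SE 0.12), Adh1 by 0.60 (SE 0.08) and Rarres2 by 0.48 (SE 0.07). Bco1, which encodes the enzyme that splits beta-carotene to retinal, measured 5.37 ± 0.33 in BALB/c and 7.57 ± 1.06 in C57Bl/6, a log2 difference of -2.20 (SE 0.41). Its adjusted p of 0.0058 rose to 0.053 with an intensity trend and a robust prior in the limma fit. Bco2, the other carotenoid oxygenase gene, differed by -0.34 (SE 0.08), named after its value was seen, and its adjusted p of 0.022 reached 0.065 without BALB/c replicate 4. The list passed (limma camera, adjusted p = 0.00228; adjusted p = 0.215 with an estimated correlation) with a median log2 difference of 0.13.

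Xenobiotic metabolism genes showed 14 increases and 4 decreases in BALB/c among 56 tested, with 38 not past the threshold and 20 higher and 5 lower adjusted over the list alone. Gstm2, a glutathione transferase gene, was higher by 1.43 (SE 0.07), and the glucuronosyltransferase genes Ugt2b5 and Ugt2b36 by 1.81 (SE 0.13) and 1.62 (SE 0.14). Cyp2c55, a cytochrome P450 gene, was lower, at -1.81 (SE 0.14). All of these have close relatives on the array. The median log2 difference was 0.24 (limma camera, adjusted p = 2.3e-05; adjusted p = 0.575 with an estimated correlation). Of 24 genes of oxidative stress and the NRF2 response, 4 were higher, 1 was lower and 19 did not pass, with 5 higher and 1 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.317). Gclc, the catalytic subunit gene of glutathione synthesis, was higher by 1.52 (SE 0.16), catalase (Cat) by 0.78 (SE 0.09), the quinone reductase gene Nqo1 by 0.73 (SE 0.13) and Gss by 0.44 (SE 0.08).

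Of 34 cell cycle genes tested, 17 were lower in BALB/c, 0 were higher and 17 did not pass, and 26 were lower and 0 higher adjusted over the list alone. Rrm2, the regulatory subunit gene of ribonucleotide reductase, measured 6.32 ± 0.11 in BALB/c and 7.32 ± 0.11 in C57Bl/6, a log2 difference of -0.99 (SE 0.08). The spindle checkpoint gene Bub1b differed by -0.62 (SE 0.08), the cyclin gene Ccne2 by -0.68 (SE 0.10) and the replicative helicase gene Mcm6 by -0.75 (SE 0.12). The list median was -0.29 (limma camera, adjusted p = 9.6e-13; adjusted p = 0.26 with an estimated correlation). With the pancreatic score in the model 12 members were lower, and within the 5 arrays rich in pancreatic transcripts 5 were lower. Of 31 DNA repair and uracil excision genes, 4 were lower, 1 was higher and 26 did not pass, with 5 lower and 1 higher adjusted over the list alone. Xrcc6, which encodes a DNA end-binding protein, was lower, at -0.37 (SE 0.07), and the list did not pass (adjusted p = 0.0584), although it did after quantile normalization of the columns (adjusted p = 0.0378). Without C57Bl/6 replicate 4 the adjusted p of that list was 0.0349, and without C57Bl/6 replicate 1 it was 0.0466.

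Of 21 cholesterol synthesis and uptake genes tested, 5 were lower in BALB/c, 0 were higher and 16 did not pass, with 10 lower and 0 higher adjusted over the list alone. Sc5d, a late enzyme gene of the pathway, differed by -0.56 (SE 0.11). Cyp51, the lanosterol demethylase gene, differed by -0.76 (SE 0.18), and its adjusted p of 0.023 reached 0.065 without BALB/c replicate 3 and 0.052 without C57Bl/6 replicate 2. The list median was -0.25 (limma camera, adjusted p = 0.000498; adjusted p = 0.523 with an estimated correlation). Of 21 lipogenesis and triglyceride genes, 3 were higher, 3 were lower and 15 did not pass, with 4 higher and 7 lower adjusted over the list alone. Me1 and the phosphatidate phosphatase gene Lpin2 (0.74, SE 0.13) were higher, and Acly (-0.41, SE 0.08), which supplies acetyl-CoA, and the desaturase gene Fads2 (-0.45, SE 0.09) were lower. That list did not pass (adjusted p = 0.879), and its mean (0.12) had the opposite sign to its median (-0.04) and its test.

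Circadian clock genes differed in both directions. Of 18 tested, 9 were higher and 2 were lower in BALB/c and 7 did not pass, with 9 higher and 3 lower adjusted over the list alone. Arntl, which encodes the activator BMAL1, measured 4.69 ± 0.18 in BALB/c and 6.94 ± 0.29 in C57Bl/6. Dbp, a target of that activator, ran the other way, at 8.18 ± 0.14 and 5.91 ± 0.53. Ciart was higher by 1.28 (SE 0.12) and Tef by 0.85 (SE 0.10), and the other decrease was that of Nfil3 (-1.29, SE 0.23), named after its value was seen. The list passed towards higher values in BALB/c (limma camera, adjusted p = 0.0179; adjusted p = 0.339 with an estimated correlation) with a median of 0.39. The hour at which the animals were killed was not given in the sources used here.

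**Figure D2:**
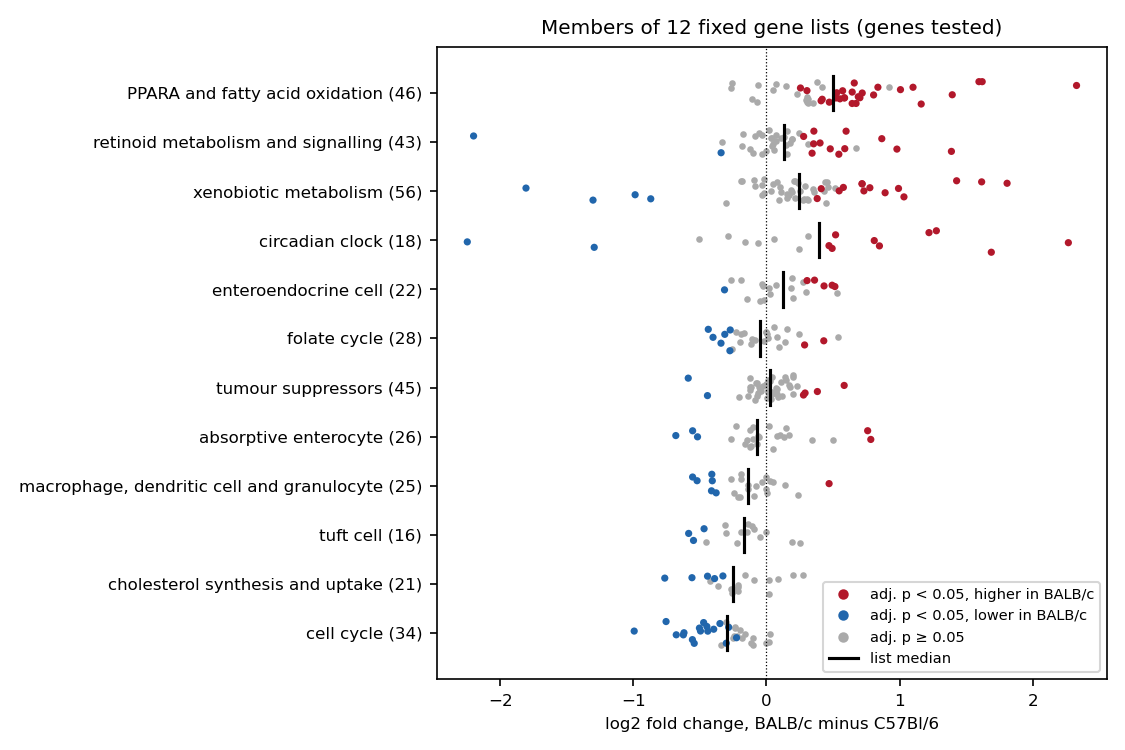
Log2 difference, BALB/c minus C57Bl/6, of each tested member of 12 gene lists, with the number tested in brackets, members past an adjusted p of 0.05 in red where higher and blue where lower, and a bar at the list median. Fatty acid oxidation genes centre on 0.50 and cell cycle genes on -0.29, while clock genes spread from -2.25 to 2.27.

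Folate cycle genes showed small differences in both directions. Of 28 tested, 2 were higher and 6 were lower in BALB/c and 20 did not pass, with 3 higher and 6 lower adjusted over the list alone. Mthfd1l, a mitochondrial folate enzyme gene, was higher by 0.43 (SE 0.07). Tyms, the thymidylate synthase gene, differed by -0.34 (SE 0.06), Qdpr by -0.40 (SE 0.08) and Aldh1l1, a formyltetrahydrofolate dehydrogenase gene, by -0.44 (SE 0.10). The adjusted p of Aldh1l1 was 0.021, rose to 0.051 with the pancreatic score in the model and reached 0.058 without C57Bl/6 replicate 4, the highest of the 5 arrays whose removal ended the call. The list did not pass (adjusted p = 0.333). Among 28 genes of methionine, choline and methylation, 1 was higher, 2 were lower and 25 did not pass, with the same counts adjusted over the list alone. Odc1, the ornithine decarboxylase gene, was higher by 0.48 (SE 0.09) on the feature used. Its other feature gave a smaller difference of 0.19, which did not pass even before adjustment (limma, unadjusted p = 0.0685). That list did not pass (adjusted p = 0.982), and its mean (0.06) and median differed in sign.

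Tumour suppressor genes numbered 45 tested, of which 4 were higher, 2 were lower and 39 did not pass, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.491). Cdx2, the intestinal homeobox gene, differed by -0.59 (SE 0.14), with an adjusted p of 0.019 that reached 0.052 without C57Bl/6 replicate 4 or BALB/c replicate 3. Of 24 Wnt target and crypt stem cell genes, the ubiquitin ligase gene Rnf43 was higher (0.52, SE 0.10), the stem cell receptor gene Lgr5 was lower (-0.41, SE 0.09) and 22 did not pass, and the same 1 and 1 were counted adjusted over the list alone (adjusted p of the list = 0.705). Apoptosis genes gave 4 higher, 2 lower and 18 not past the threshold of 24, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.916), with a mean (0.02) opposite in sign to its median and test. Pmaip1, which encodes a BH3-only protein, was higher by 0.62 (SE 0.14), with an adjusted p of 0.017 that reached 0.052 without C57Bl/6 replicate 2 and 0.051 without BALB/c replicate 3. Among 12 genes of PPARG, PPARD and their partners, 3 were lower and 9 did not pass, with 1 higher and 3 lower adjusted over the list alone and an adjusted p of 0.3 for the list. The 3 were Ppargc1b (-0.30), Ncoa1 (-0.32) and Ppard (-0.40), and the call of Ppard (adjusted p = 0.049) was lost whichever of the 8 arrays was left out, reaching 0.12 without C57Bl/6 replicate 4. Ppargc1b reached 0.07 without BALB/c replicate 3 and Ncoa1 reached 0.068 without BALB/c replicate 2.

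Epithelial cell types were compared through marker genes. Of 26 absorptive enterocyte genes, 2 were higher, 3 were lower and 21 did not pass, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.705). The peptide transporter gene Slc15a1 (0.78, SE 0.11) and the neutral amino acid transporter gene Slc6a19 (0.76, SE 0.12) were higher, and the sterol transporter gene Npc1l1 (-0.68, SE 0.10) and the lactase gene Lct (-0.52, SE 0.12) were lower. Of 16 tuft cell genes, 3 were lower and 13 did not pass, with 1 higher and 5 lower adjusted over the list alone (limma camera, adjusted p = 0.00822; adjusted p = 0.339 with an estimated correlation). The 3 were Trpm5 (-0.58, SE 0.07), Dclk1 (-0.55, SE 0.11) and Avil (-0.47, SE 0.10). Enteroendocrine genes gave 5 higher, 1 lower and 16 not past the threshold of 22, with 7 higher and 1 lower adjusted over the list alone, including the hormone genes Gip (0.49, SE 0.07) and Sct (0.51, SE 0.09). That list passed (adjusted p = 0.035; adjusted p = 0.215 with an estimated correlation) but not with the pancreatic score in the model (adjusted p = 0.0646), without C57Bl/6 replicate 3 (0.0714) or without BALB/c replicate 3 (0.0571). Of 16 Paneth cell and antimicrobial genes, 4 were higher, 2 were lower and 10 did not pass, with 6 higher and 3 lower adjusted over the list alone. Besides Pla2g2a and Mptx1, the defensin gene Defa24 (-1.32, SE 0.11), a member of a family of near-identical genes, and the angiogenin gene Ang4 (-1.06, SE 0.19) were lower. The Paneth list had an adjusted p of 0.0883, which fell to 0.00796 without C57Bl/6 replicate 1, to 0.0374 without BALB/c replicate 1 and to 0.0435 with each array centred on its median. Among 13 goblet cell genes the mucin genes Muc4 (-0.88, SE 0.14) and Muc13 (-0.29, SE 0.08) were lower and 11 did not pass, with 2 higher and 2 lower adjusted over the list alone and an adjusted p of 0.714. Muc13 had an adjusted p of 0.047, which reached 0.12 without BALB/c replicate 3 and 0.098 with the pancreatic score in the model. Of 16 gastric and Brunner gland genes 0 passed the limma test by either adjustment and 3 had an unadjusted p under 0.05 (list adjusted p = 0.484), and their mean (-0.09) was opposite in sign to their median (0.10) and test. The smallest p in that list belonged to Pdx1 (0.40, adjusted p = 0.06).

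Exocrine pancreas genes varied widely within strains. The mean log2 value of the 18 genes tested was 9.92 and 9.76 in C57Bl/6 replicates 1 and 4 and 11.4, 10.3 and 10.8 in BALB/c replicates 2, 3 and 4. It was 5.11 and 5.26 in C57Bl/6 replicates 2 and 3 and 5.05 in BALB/c replicate 1. The strain means were 9.39 ± 2.92 in BALB/c and 7.51 ± 2.69 in C57Bl/6 (log2, mean ± SD, n = 4 each; two-sided exact permutation p = 0.229, where 0.0286 is the smallest possible). Cpb1, a procarboxypeptidase gene, averaged 11.84 in the 5 arrays with high scores and 3.49 in the other 3, Ctrb1, a chymotrypsinogen gene, 12.15 and 4.88, and Cel, a lipase gene, 11.37 and 3.47. In 16 of the 18 genes the 5 arrays lay above the 3, and Zg16 and Spink1 were the exceptions. Cpb1, Ctrb1, Cel and Zg16 were named after their values were seen. By strain 0 of the 18 passed the limma test by either adjustment, 2 had an unadjusted p under 0.05, and the smallest p belonged to Ctrc (2.49, SE 0.93). The list median was 2.21 (limma camera, adjusted p = 0.0394; adjusted p = 0.821 with an estimated correlation). The list did not pass after quantile normalization (0.0592), with array weights (0.239) or in 5 of the 8 fits that left out an array, with the highest adjusted p, 0.367, without C57Bl/6 replicate 2.

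**Figure D3:**
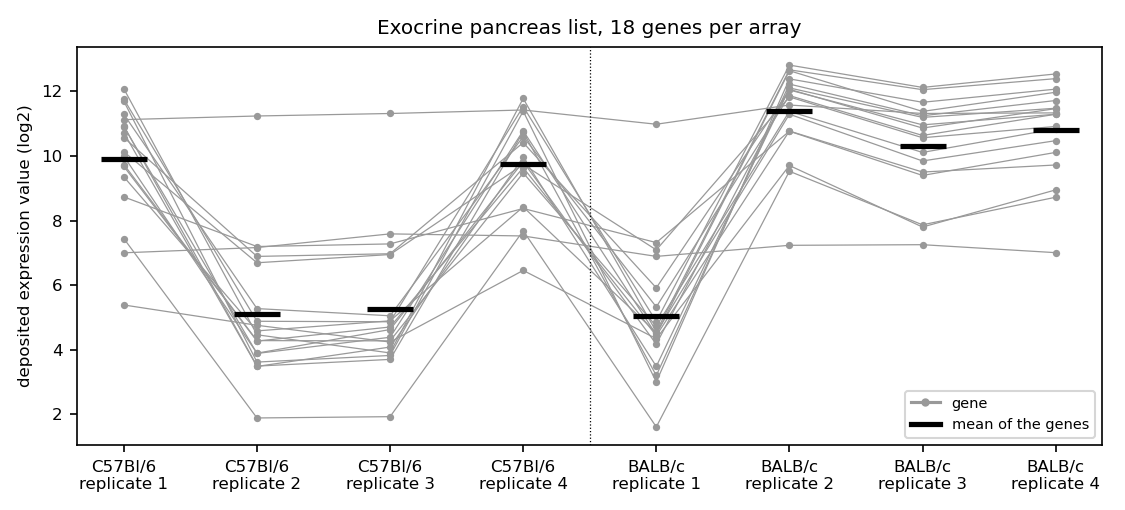
Deposited log2 values of 18 exocrine pancreas genes (grey, 1 line per gene) in each of the 8 arrays, with a black bar for the mean of the genes, C57Bl/6 arrays on the left and BALB/c arrays on the right. The mean lies between 9.76 and 11.4 in 5 arrays and between 5.05 and 5.26 in 3, and both strains hold arrays of both kinds.

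Of 25 macrophage, dendritic cell and granulocyte genes, 6 were lower, 1 was higher and 18 did not pass, with 7 lower and 2 higher adjusted over the list alone (limma camera, adjusted p = 0.00961; adjusted p = 0.339 with an estimated correlation). The mannose receptor gene Mrc1 (-0.41, SE 0.07), the complement gene C1qc (-0.55, SE 0.10) and Cd68 (-0.41, SE 0.09) were lower. The eosinophil receptor gene Ccr3 (0.47, SE 0.11) was the member that was higher, with an adjusted p of 0.02 that reached 0.057 without BALB/c replicate 2 and 0.054 without BALB/c replicate 3. By either adjustment 0 genes passed the limma test among 24 T and NK cell genes (list adjusted p = 0.763), 9 mast cell genes, 20 B and plasma cell genes and 28 inflammatory cytokine and NF-kB genes (list adjusted p = 0.291). At an unadjusted p under 0.05 these lists held 4, 2, 4 and 5 genes. The smallest p belonged to Cd8b1 (0.27), Tpsb2 (0.24), Blk (0.31) and Ccl20 (0.86), in that order of lists. The immunoglobulin gene Ighm of the B and plasma cell list did not pass on the feature used (0.57, adjusted p = 0.11, and 0.041 without BALB/c replicate 4), but passed lower in BALB/c on its feature with the largest variance (-1.79, adjusted p = 0.0043), against the direction of the list. The B and plasma cell list passed with a median of 0.19 (adjusted p = 0.0112; adjusted p = 0.608 with an estimated correlation), but not with the pancreatic score in the model (0.0668), with the most variable feature of each gene (0.0597) or without BALB/c replicate 2 (0.111). The mast cell list passed with a median of 0.20 (adjusted p = 0.0429; adjusted p = 0.301 with an estimated correlation) but not with the pancreatic score (0.0843), after quantile normalization (0.0745) or with the stricter filter (0.378), and it was lost in 5 of the 8 fits that left out an array, up to 0.101 without C57Bl/6 replicate 4.

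Class II histocompatibility genes went both ways, with H2-Ea and H2-Eb2 (0.60, SE 0.09) higher and H2-Ab1 (-1.68, SE 0.11) and the invariant chain gene Cd74 (-0.56, SE 0.12) lower among 14 tested, 10 not past the threshold, and 2 higher and 3 lower adjusted over the list alone. The list did not pass (adjusted p = 0.705), and its mean (0.23) had the opposite sign to its median (-0.13) and test. Class I and antigen processing genes gave 3 higher, 3 lower and 12 not past the threshold of 18, with 6 higher and 3 lower adjusted over the list alone (list adjusted p = 0.916). Besides H2-Q2, H2-M2 (-0.93, SE 0.15) was lower, and H2-T24 (0.95, SE 0.14) and the peptide transporter gene Tap2 (0.37, SE 0.08) were higher. Histocompatibility genes are among the most variable between strains, and their probes can bind one allele better than another. Of 30 interferon response genes, 4 were lower, 1 was higher and 25 did not pass, with the same counts adjusted over the list alone. Gbp4 was higher (0.88, SE 0.09), and Ifit3 (-1.15, SE 0.16) and Bst2 (-0.39, SE 0.08) were lower. The interferon list passed (adjusted p = 0.0499; adjusted p = 0.821 with an estimated correlation), but not after either rescaling (0.0709 and 0.0855), with the pancreatic score (0.1) or without C57Bl/6 replicate 3 (0.376), C57Bl/6 replicate 4 (0.274), BALB/c replicate 2 (0.0905) or BALB/c replicate 3 (0.357).

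Of 21 fibroblast and matrix genes, 3 were lower, 1 was higher and 17 did not pass, with 8 lower and 1 higher adjusted over the list alone, and the proteoglycan gene Bgn was lower (-0.48, SE 0.09). That list passed (limma camera, adjusted p = 0.0291; adjusted p = 0.406 with an estimated correlation), but not after quantile normalization of the columns (0.0592), without C57Bl/6 replicate 1 (0.0788) or without C57Bl/6 replicate 3 (0.0556). Of 21 smooth muscle genes only Actc1, a cardiac actin gene, was higher (1.20, SE 0.07), also over the list alone (list adjusted p = 0.402). Of 16 endothelial genes 2 were lower, including Plvap (-0.46, SE 0.08), also over the list alone (list adjusted p = 0.982), with a median (0.05) opposite in sign to the mean and test. Of 20 enteric neuron and glia genes, Gal (0.73, SE 0.20) passed over all genes, with an adjusted p of 0.038 that was lost in 6 of the 8 fits that left out an array, reaching 0.102 without BALB/c replicate 2, and 0 passed over the list alone. The neuron list had an adjusted p of 0.0285 (adjusted p = 0.215 with an estimated correlation), and 0.0603 with the pancreatic score, 0.0714 after quantile normalization, 0.0556 without C57Bl/6 replicate 3 and 0.0571 without BALB/c replicate 3. Of 11 adipocyte genes, Fabp4 (0.45, SE 0.12) was higher by both adjustments, with an adjusted p of 0.035 that became 0.084 with the pancreatic score and 0.091 without BALB/c replicate 4, and 10 did not pass. The adipocyte list passed with a median of 0.20 (adjusted p = 0.00822; adjusted p = 0.215 with an estimated correlation). Of 4 erythroid genes, too few for a list test, 0 passed the limma test and 1, Fech (0.30, SE 0.10), had an unadjusted p under 0.05. Iron handling gave 1 higher, 1 lower and 18 not past the threshold of 20, with 2 higher and 3 lower adjusted over the list alone (list adjusted p = 0.803), and a median (0.01) opposite in sign to its mean and test. Immediate early and heat shock genes gave 2 higher, 2 lower and 21 not past the threshold of 25, with 2 higher and 3 lower adjusted over the list alone (list adjusted p = 0.739). The heat shock gene Hsph1 (-1.32, SE 0.28) was lower and Fos (0.51, SE 0.11) was higher. The adjusted p of Hsph1, 0.014, became 0.075 with an intensity trend and a robust prior in the limma fit.

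Over all lists, 17 of the 38 tested passed camera with its preset correlation and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05 and the smallest adjusted p was 0.101. By fry, which asks whether the genes of a list move on balance one way, 18 passed, and 32 passed its mixed test for change in either direction. The number that passed camera was 11 without C57Bl/6 replicate 3 and 11 with the pancreatic score in the model.

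Called genes lay beside one another along the chromosomes more often than permuted calls did. Of the called genes, 19.4% had a neighbouring tested gene called in the same direction, against a mean of 10.4% and a highest value of 14.6% in 10000 permutations (p = 1e-04, the smallest they can give). The longest runs held 4 genes, all higher in BALB/c: Capg, Elmod3, Retsat and Tgoln1 on chromosome 6, and Ugt2b35, Ugt2b36, Ugt2b5 and Ugt2b37 on chromosome 5. Apart from Ugt2b36 and Ugt2b5, these genes were named after their values were seen. The X chromosome held fewer called genes than the rest, 28 of 502 (5.58% against 10.6%; Fisher's exact test, adjusted p = 0.00287), and chromosome 3 held more, 109 of 790 (13.8% against 10.3%; adjusted p = 0.0231). The number of such chromosomes, 2 of 20, fell to 0 with the pancreatic score in the model, and without BALB/c replicate 2, BALB/c replicate 3 or BALB/c replicate 4. It fell to 1 without BALB/c replicate 1 or without C57Bl/6 replicate 1, 2 or 3. Chromosome 3 did not pass in 7 of the 8 fits that left out an array, with an adjusted p of up to 0.392 without BALB/c replicate 2, and passed at 0.0499 without C57Bl/6 replicate 1. The X chromosome did not pass without C57Bl/6 replicate 1 (0.173) or without BALB/c replicate 2 (0.135), 3 (0.146) or 4 (0.0815). At an unadjusted p under 0.05 there were 3. Of the 200 tested genes nearest to Mthfr on chromosome 4, 23 (11.5%) were called against 10.4% elsewhere (two-sided Fisher's exact test, p = 0.641).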

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

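The test of pancreatic tissue in the pieces was chosen after the pattern was seen but before the values of its genes were. The tests of a strain difference as its whole cause, of the hour of killing, of food intake and of pancreatic tissue behind the clock genes were chosen after the results they bear on had been seen. In 15 of 354 groups of 4 arrays 1 array stood apart from the other 3 by Dixon's criterion, against 17.7 by chance at 1 group in 20. The number after each item is the gap to the nearest array as a share of the range.

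The exocrine pancreas score was low in BALB/c replicate 1 (0.832), at 5.05 against a median of 10.8 in the other BALB/c arrays. C57Bl/6 replicate 1 stood apart for Slc34a2 (0.977), Hsph1 (0.880), Acot1 (0.870) and Cdca7 (0.838), with Hsph1 at 9.18 against a median of 7.75. C57Bl/6 replicate 2 stood apart for Ciart (0.903) and Mcm6 (0.836). BALB/c replicate 1 stood apart for Prox1 (0.855) and Hsp90aa1 (0.838), BALB/c replicate 2 for H2-Ea (0.837), and BALB/c replicate 4 for Fads2 (0.898). BALB/c replicate 3 stood apart for Ppard (0.926), Stmn2 (0.890), Xrcc6 (0.876) and Cyp51 (0.839).

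Pancreatic transcripts were high in 5 of the 8 arrays, where Cpb1 and Ctrb1 averaged 11.8 and 12.2. A strain difference as the whole cause is argued against by the range of the score within C57Bl/6, 4.81 on the log2 scale, beyond the difference of the strain means of 1.88. The median ratio of fold changes with and without the score was 0.977 over the 1747 called genes, so these fold changes depended little on the score. A call needs a small spread within strains, which genes that follow the score do not have, so a ratio near 1 was likely beforehand. With the score in the model 68.1% of the calls were kept, and the calls lower in BALB/c fell from 1014 to 666. A part of the pancreatic transcripts in the number of calls therefore stays open. Pancreatic tissue carried with some pieces of duodenum stays open by the rule set beforehand. The 9 acinar genes outside the list differed by a median of 0.984, just under the 1 that was set. In the other 3 arrays 0 of them lay above the median of all genes. Ctrl (a relative of Ctrb1), Sycn, Serpini2 and Cuzd1 were higher by 4.14 to 7.32 and the other 5 by under 1. In 8 of the 9 genes the 5 arrays with high scores all lay above the other 3. Islet genes differed by a median of 0.351 over the 3 tested, too few and too weak to decide whether islets came along.

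Clock and fatty acid oxidation genes differed together between the strains. With the pancreatic score in the model 34 of the 38 called genes of both lists stayed past the threshold. These genes were chosen because they were called, which needs a small spread within strains, so this was likely beforehand. The count therefore cannot decide on pancreatic tissue in some arrays. A different hour of killing for each strain may account for the clock genes, since all 11 that were called followed opposite arms, with Arntl and Nfil3 lower and 9 genes of the Dbp arm higher, but the hour cannot be told apart from the strain because no hour was given. Less food before killing in BALB/c also stays open, since the 6 lipogenic genes that fasting lowers had a median of -0.27 with 1 called lower and 0 higher, between the outcomes set for either answer, while Me1, a lipogenic gene left out of the 6, was higher by 2.07. A strain difference in the clock or in lipid metabolism was not tested.

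Called genes lay beside called genes of the same direction. Probes shared between duplicated neighbours are argued against as the whole cause, since 16% of called genes still had such a neighbour when pairs with the same leading letters were not counted, against a mean of 9.62% in 10000 permutations (p = 1e-04, the smallest they can give). Blocks of linked strain variants, in genes or under their probes, are a candidate explanation, since 30.6% had a call of the same direction 3 to 5 genes away, against 27.2% (permutation p = 0.0087). Neighbours expressed together whatever the strain stay open: 0 of 18 splits with both strains on either side reached the neighbour correlation of the strains (0.0561, highest other 0.0454). With 18 splits a share under 0.05 cannot be had once the real one is counted, so the outcome set beforehand for excluding this was too easily met.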

How the results depend on the processing

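The alternatives that used the pancreatic score were chosen after seeing the data. The 1747 called genes kept their direction in every fit that tested all of them. The count of genes stayed between 1254 and 2046 under the other scalings, filters, feature rules, variance models, array weights, replicate block and pancreatic covariate, with 1289 genes under the block. Without 1 array the count of genes ranged from 1191 to 1623, lists from 11 to 18 and chromosomes from 0 to 2. With all 35528 features tested in place of genes, 1345 features passed, a count of another unit. Fewer genes passed by construction at an adjusted p under 0.01 (704) and at an unadjusted p with a 1.5-fold change (467), and with fewer arrays, 566 in the high and 175 in the low pancreatic arrays, whose lone BALB/c array was assumed to vary like the C57Bl/6 arrays. Lists numbered 11 with the covariate, 11 in the high arrays, 7 in the low arrays and 0 with an estimated correlation. Chromosomes numbered 0 at an adjusted p under 0.01 and 0 with the covariate, and the cause was not tested. Ighm reversed to -1.79 (adjusted p = 0.0043) on its feature with the largest variance, which is a different probe set, and the exocrine pancreas median reversed to -0.11 with the covariate, which removes the score, and to -0.12 in the low arrays. The share of calls lower in BALB/c was 58.0%, and 49.4% and 67.1% after quantile normalization and median centring. Of 176 named genes, 157 kept their side of the threshold under the block (16 lost, 3 gained) and 154 with the covariate (21 lost, 1 gained). Deviations of same-numbered arrays from their strain means correlated at -0.52, -0.40, -0.08 and 0.29, and only number 4 correlated best with its own. In numbers 1, 2 and 3 the pancreatic score was high in one strain and low in the other, and in number 4 it was high in both. These correlations therefore cannot show whether the replicate numbers mark a shared block. The scale for values not logged was not run, since the values were logged. Signal near the dim end limits folds of weak genes.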

Other observations

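The genes of this part were chosen after their values were seen. Of 16 NLR and NAIP sensor genes tested, 5 were lower in BALB/c, 0 were higher and 11 did not pass in the limma fit, with the same counts after both rescalings. Nlrp1b, which encodes an inflammasome sensor, was lower, at -1.84 (SE 0.09), Nlrp9b at -1.67 (SE 0.14) and Naip6 at -0.72 (SE 0.11). Pycard, the adaptor gene of inflammasomes, measured 6.29 ± 0.18 in BALB/c and 7.77 ± 0.09 in C57Bl/6 (log2, mean ± SD, n = 4 each), and Ly96, the coreceptor gene of the endotoxin receptor, differed by -1.41 (SE 0.11). The DNA sensor gene Aim2 ran the other way, at 6.03 ± 0.17 and 4.23 ± 0.08. The NLR and NAIP genes have close relatives on the array, and probe binding can differ between alleles. Each of these 6 named genes passed in all 8 fits that left out an array.

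Other single genes passed as well. S100g, which encodes the calcium-binding protein calbindin-D9k, was higher in BALB/c by 1.84 (SE 0.20), the metallothionein gene Mt1 by 1.15 (SE 0.23) and the water and glycerol channel gene Aqp3 by 1.80 (SE 0.09). The sodium-hydrogen exchanger gene Slc9a3 (-1.29, SE 0.13) and the sulfate transporter gene Slc26a2 (-1.44, SE 0.10) were lower. Of 6 Ugt2b genes 5 were higher and 0 were lower, and of 7 Apol genes 3 were lower and 0 higher, 2 lower after quantile normalization. The histidine ammonia-lyase gene Hal was higher by 1.87 (SE 0.09), and Prodh (-0.91, SE 0.10) and Aldh18a1 (-0.93, SE 0.10) were lower. Mogat1, a monoacylglycerol acyltransferase gene, was higher by 1.89 (SE 0.21) over a C57Bl/6 mean of 3.21 near the dim end, and Prom1, a membrane protein gene used as a stem cell marker, was lower, at -1.51 (SE 0.09).

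The number of called genes was set against the other splits of the 8 arrays into 4 and 4. The strains gave 1747 and the highest other split gave 2, so that 1 of 35 splits reached the real count. That is the smallest share 35 splits can give, so chance is argued against but not excluded. Every other split mixes the strains, which widens the spread within its sides and keeps its count low. Nor does the count separate strain from anything else that the arrays of a strain share. Some features without a named gene also differed. Of 35528 features tested alike, 1345 passed the limma test. Among them were 332 of the 12141 features with no listed gene, a smaller share than over all features, and 61 of the 1620 with several.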
